A study of Homo sapiens with 6 samples.

How the data were processed

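RNA of 6 samples of MDA-MB-231 cells in the EpCAMhi form was measured, 3 after negative control siRNA and 3 after UPF2 siRNA (100 nM, 72 h), per the labels. The labels number the replicates 1 to 3 in each group and do not say whether they were separate cultures or shared a day. Poly(A) RNA was made into strand-specific libraries, and the control and UPF2 siRNA pools were sequenced on separate lanes, per the labels' protocols. The labels give an RNA integrity number above 9 for every sample.

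The authors deposited exon counts as whole numbers per exon bin, with overlapping genes joined into 1 entry, per the file headers. HISAT2 2.2.0, HTSeq, StringTie 2.1.2 and kallisto 0.46 with GRCh38 are listed per the submitters' processing notes, which state neither command lines nor the strand setting of the counting. The deposited TPM of 190069 reference transcripts sums to the same total in every library, as TPM does. The deposited assembled-transcript abundance is a signal on a TPM-like scale, with library sums from 0.871 to 1.347 times the TPM total, so it was rescaled in a way that the files do not state. It holds 241840 transcripts, of which 14758 have no reference identifier. The positions of transcripts come from the deposited merged annotation, which names Ensembl release 98 of GRCh38 as its guide, per the file headers. Gene symbols came from a reference list of gene names or, where it held none, from the same annotation and then from GENCODE release 29. Biotypes came from GENCODE release 29, which gave a biotype to 89.1% of the transcripts in the TPM table. The exon bins of 74.9% of the gene entries could be rebuilt from the merged annotation. The counting may have used another annotation release, which was not tested.

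The plan was to test estimated counts per gene and per transcript, but the reference table holds TPM only. Gene counts were therefore the exon counts summed per gene entry, the fallback fixed before the data were examined, and transcripts were tested with limma on log2(TPM + 0.5). Of 56557 gene entries, 2475 join overlapping genes and hold 23.0% of the counts, and they are named as counted together. Genes were filtered with edgeR's filterByExpr, scaled with TMM and tested with edgeR's quasi-likelihood F test (edgeR 4.0.16, R 4.3.3), with Benjamini-Hochberg adjusted p under 0.05 as the threshold. Transcripts were kept at a value of at least 0.5 in at least 3 libraries and tested with limma 3.58.1. Exon usage was tested with edgeR's diffSpliceDGE, per bin and per gene (Simes). The groups were compared 3 against 3 with no covariate. Library sizes in these tests are sums of exon counts, and their size limits counting error only.

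The 25 gene lists were fixed before the data were examined: NMD factors, exon junction complex, reported NMD targets, small nucleolar RNA host genes, SR proteins and splicing regulators, integrated stress response, unfolded protein response, p53 targets, interferon-stimulated genes, antigen presentation by MHC class I, ligands of immune receptors, inflammatory cytokines, cell cycle, DNA repair, apoptosis regulators, epithelial, mesenchymal, immune, fibroblast and endothelial markers, cholesterol synthesis, glycolysis and hypoxia, mitochondrially encoded transcripts, histones, and the double-stranded RNA pathway. They share members, such as GAS5 and ATF4. They were tested with limma's camera at a preset correlation of 0.01 on log2 CPM (prior count 2), and again with an estimated correlation and with fry. Shares of TPM were compared with exact permutation tests.

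The rule for named genes was also fixed then. It took UPF2, the 8 protein-coding genes highest and the 8 lowest by log2 fold change among those past the test with a mean of at least 1 CPM and no overlap of the groups, up to 2 members per list and direction past the test or else the most abundant member, the 8 genes with the smallest Simes p for exon usage, and the 5 highest and lowest transcripts past the test. Where nothing passed over all genes, list members past the test adjusted over the list alone, and transcripts with small p values, were named after their values were seen. The same rule was then applied without UPF2 siRNA replicate 1. The result for 1 list member is not reported here.

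Alternatives were other scalings (DESeq2 1.42.0 size factors), filters, pseudocounts of 0.1 and 1, tools, a replicate block and leaving out each library. Added after the data were seen were gene TPM sums, removal of each library's trend over transcript length (lowess span 0.3), library quality weights, DESeq2 on 5 libraries, other scalings of the abundance, and tests of gene classes by annotated type. The 5′ to 3′ ratio compared the first and last 25% of exon bins by order in genes with at least 8 bins, 5 CPM and 50 counts at each end.

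Each test was run on simulated data first. For genes, edgeR recovered 49% of 2-fold and 100% of 4-fold changes, with 5.7% of its calls on unchanged genes, and DESeq2 74% and 99%, with 23.1% of its calls on unchanged genes (19895 genes). For annotated transcripts, limma recovered 0%, 36% and 78% of 2-, 4- and 8-fold changes (59360 transcripts), and for assembled ones 0%, 10% and 68% (66933 transcripts). For exon usage, 50% of 4-fold changes were recovered where each bin kept its own spread, with 47.3% of calls on unchanged bins, and 51% where spread followed abundance, with 10.4% of calls on unchanged bins (316206 bins). In a simulation of the lists, the raised list was called and 0 of the unchanged lists were, by camera with either correlation and by fry. Genes were simulated independently of each other and without a deviating library, so it could not show false calls that arise from either. Every column of the deposited tables was used.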

Results

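The series measured poly(A)-selected RNA in MDA-MB-231, an established human breast cancer cell line, in the form that the labels call EpCAMhi. Cells received 100 nM of negative control siRNA (3 libraries) or of UPF2 siRNA (3 libraries) and were sampled after 72 h. UPF2 is a core factor of nonsense-mediated mRNA decay (NMD), the pathway that degrades transcripts with premature stop codons. The series title places the knockdown in work on breast cancer immunotherapy by tumor-targeted gene silencing, and the comparison asks which transcripts changed when UPF2 was depleted. Exon counts summed to 302161116, 269705672 and 257289950 in control replicates 1, 2 and 3, and to 224744506, 312035701 and 292565206 in UPF2 siRNA replicates 1, 2 and 3. A read that spans several exon bins is counted in each of them, so these totals exceed the number of reads. The control and UPF2 siRNA pools ran on separate lanes per the labels, so the lane and the siRNA cannot be told apart in any comparison given here.

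UPF2 mRNA (ENSG00000151461, chromosome 10, 11920022 to 12043170, GRCh38) fell in all 3 UPF2 siRNA libraries. It stood at 34.1, 29.1 and 25.7 CPM (exon counts normalised to library size) in the control libraries and at 6.79, 6.61 and 7.57 CPM in the UPF2 siRNA libraries. The means were 29.7 ± 4.20 CPM (SD, n = 3) and 6.99 ± 0.51 CPM (SD, n = 3), so 23.6% of the control level remained. The log2 fold change was −2.09 (SE 0.165), with an edgeR adjusted p of 0.0318 over 19895 genes. An exact permutation test of the CPM values gave p = 0.1, 2-sided, the smallest value that 3 against 3 libraries allow. The protein-coding UPF2 transcript ENST00000357604 went from 11.7 ± 2.25 to 2.83 ± 0.745 TPM, the deposited transcript abundance (SD, n = 3 each). The edgeR call of UPF2 was lost when any library other than UPF2 siRNA replicate 1 was left out, with log2 fold changes from −2.18 to −1.97 and adjusted p values from 0.114 to 0.468. It was lost as well on gene TPM sums (log2 fold change −1.54, limma adjusted p = 0.352).

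**Figure D1:**
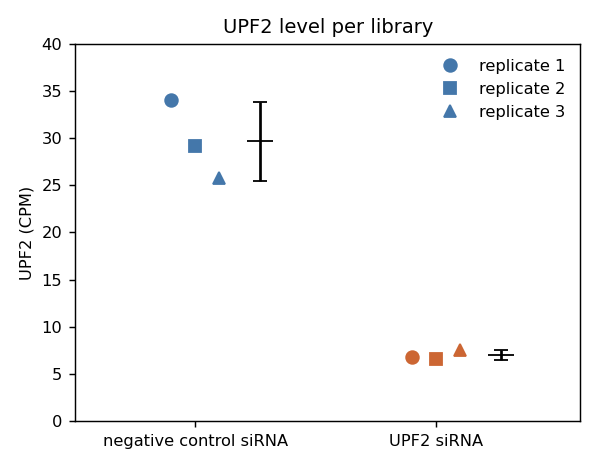
UPF2 level in CPM (vertical axis) in each of the 6 libraries, by siRNA (horizontal axis). Symbols mark the replicate number, and black bars give the mean and SD of 3 libraries: the control libraries lie between 25.7 and 34.1 CPM and the UPF2 siRNA libraries between 6.61 and 7.57 CPM.

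UPF2 siRNA replicate 1 stood apart from the other 5 libraries. In 2586 genes with transcripts over 3000 nt, its median log2 ratio of 5′ to 3′ exon counts was −1.65 relative to the mean of the other libraries, which themselves ranged from −0.16 to 0.17. Genes with transcripts under 500 nt were higher in it by a median of 0.64 on the log2 scale relative to the mean of the 6 libraries, and genes with transcripts over 4000 nt deviated by −0.50. EPCAM, the epithelial adhesion molecule that gives these cells their name, measured 548 CPM in this library and between 1603 and 2276 CPM in the other 5. The biological coefficient of variation was 0.27 with all 6 libraries and 0.166 without this one. Counts and gene lists are therefore also given without it, a choice made after the data were seen and referred to as the 5-library fit.

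**Figure D2:**
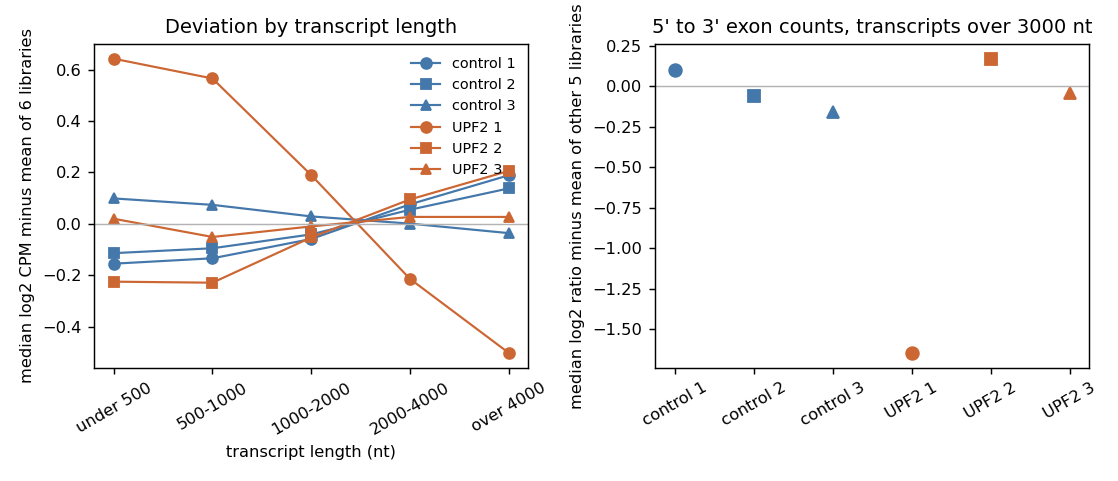
Left, the median deviation of log2 CPM from the mean of the 6 libraries (vertical axis) for genes in 5 classes of transcript length (horizontal axis), with 1 line per library. Right, the median log2 ratio of 5′ to 3′ exon counts in 2586 genes with transcripts over 3000 nt, relative to the mean of the 5 libraries other than UPF2 siRNA replicate 1. That library lies at −1.65 and the others lie between −0.16 and 0.17.

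Beyond UPF2 itself, no single gene passed the test over all genes in the 6 libraries. FOS, an immediate early transcription factor, measured 6.21 ± 2.35 CPM under control siRNA and 46.6 ± 15.8 CPM under UPF2 siRNA (SD, n = 3 each; log2 fold change 2.91, edgeR adjusted p = 0.172). ADM, which encodes the secreted peptide adrenomedullin, measured 91.0 ± 8.19 and 220 ± 50.6 CPM (log2 fold change 1.28, edgeR adjusted p = 0.178). MMP9, a secreted gelatinase, measured 17.9 ± 1.88 and 5.77 ± 1.19 CPM (log2 fold change −1.63, edgeR adjusted p = 0.172). With edgeR, 0 of 19895 genes were higher and 1, UPF2, was lower under UPF2 siRNA. At an unadjusted p under 0.05, 887 genes were higher and 542 lower. These counts were 433 and 184 without control replicate 2, 605 and 268 without control replicate 3, 1457 and 1177 without UPF2 siRNA replicate 1, 1635 and 856 without UPF2 siRNA replicate 2 and 665 and 328 without UPF2 siRNA replicate 3. The 3 and 3 library values did not overlap in 15.6% of genes, where chance gives 10%. limma-voom called 0 higher and 1 lower, and DESeq2 called 115 higher and 36 lower.

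In the 5-library fit, 53 genes rose and 5 fell with edgeR, and 48 of these 58 genes were among the 151 that DESeq2 called in the 6 libraries. The rule for named genes, applied to this fit after the data were seen, gave FOS (log2 fold change 2.67, adjusted p = 0.0217), TSPAN2 (1.38), ZNF875 (1.19), CHMP4C (1.18), FSD1L (1.12), PDRG1 (1.09), ADM (1.08, adjusted p = 0.0151) and ZFAND2A (1.07) as the protein-coding genes that rose most. ZFAND2A encodes an arsenite-inducible, proteasome-associated protein, and CHMP4C a component of the ESCRT-III membrane scission machinery. UPF2 (−2.06), MMP9 (−1.70, adjusted p = 0.0211), TAGLN3 (−1.46), BCL2A1 (−1.24) and MPP4 (−0.99) fell. BCL2A1, an antiapoptotic BCL2 relative, measured 18.9 CPM in UPF2 siRNA replicate 1, within the controls' range, against 7.08 and 6.98 CPM in UPF2 siRNA replicates 2 and 3. The 58 genes comprised 29 protein-coding genes, 10 transcribed pseudogenes and 12 entries in which overlapping genes are counted together, among other types. Among those chosen after their values were seen, the decay factor SMG9 went from 91.8 ± 8.73 to 165 ± 19.9 CPM (SD, n = 3 each; log2 fold change 0.845, edgeR adjusted p = 0.274). In the 5-library fit its log2 fold change was 0.95 (edgeR adjusted p = 0.0211). Leaving out any other single library gave 0 higher and 0 lower genes.

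Genes reported before as NMD targets were higher under UPF2 siRNA as a group. Of 30 listed and measured genes, 28 had a positive log2 fold change, with a median of 0.41, and 23 in the 5-library fit, with a median of 0.40. GAS5, a long non-coding RNA that hosts small nucleolar RNAs, measured 449 ± 61.0 and 1210 ± 334 CPM (SD, n = 3 each; log2 fold change 1.43, SE 0.224). SNHG15, counted together with SNORA9, had a log2 fold change of 1.25, and UPF3B, itself an NMD factor, one of 1.23. ATF4, the main transcription factor of the integrated stress response, measured 181 ± 21.5 and 362 ± 55.0 CPM (SD, n = 3 each; log2 fold change 1.00). The DNA damage-inducible genes GADD45B and GADD45A had log2 fold changes of 1.14 and 0.75, and the chaperone regulator BAG1 one of 1.06. Adjusted over the list alone, these 7 and ZFAS1 (counted with SNORD12 and other overlapping genes) passed the test, 8 higher and 0 lower. In the 5-library fit the log2 fold changes were smaller for SNHG15 (0.67), UPF3B (0.70), BAG1 (0.66), GADD45A (0.50) and ZFAS1 (0.71, against 1.07). The cell cycle inhibitor CDKN1A was the clearest exception, at −0.39, with an edgeR adjusted p of 0.662. Over all genes tested, 0 of the 30 passed with 6 libraries, and 3 (GAS5, ATF4 and ZFAS1) rose in the 5-library fit. There, 14 passed when adjusted over the list alone. Limma's camera called the list upward at an adjusted p of 1.21e-06 (1.97e-04 in the 5-library fit), and adjusted p = 0.76 with an estimated correlation.

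**Figure D3:**
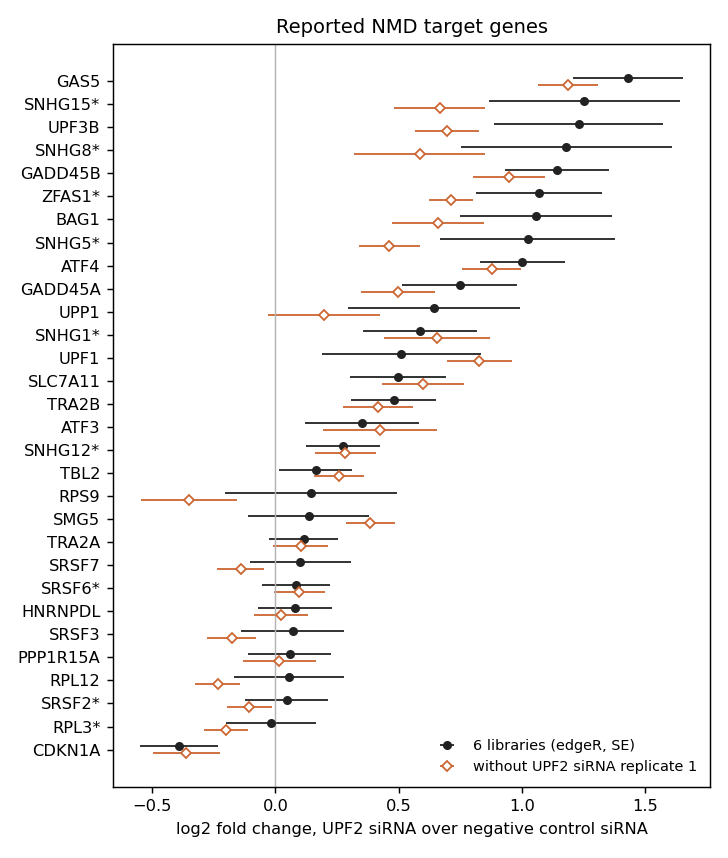
Log2 fold change of UPF2 siRNA over negative control siRNA (horizontal axis) for the 30 measured genes of the list of reported NMD targets (vertical axis). Filled circles with SE bars come from edgeR on 6 libraries and open diamonds from the fit without UPF2 siRNA replicate 1; an asterisk marks genes counted together with overlapping genes. In the 6 libraries 28 of the 30 genes lie above 0.

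Host genes of small nucleolar RNAs tended to be higher, although 19 of the 22 measured were counted together with the small RNAs or genes that overlap them. The list shares GAS5, ZFAS1, SNHG15 and other members with the NMD targets, so it is not an independent result. Of the 22, 15 had a log2 fold change above 0, with a median of 0.7 (14 and 0.4 in the 5-library fit). Adjusted over the list alone, 8 were higher and 0 lower, among them SNHG29 (log2 fold change 0.84, counted with SNORD49A and SNORD49B) and EPB41L4A-AS1 (0.83, and 0.53 in the 5-library fit), the latter counted alone. The entry with the largest change, 92.1 ± 14.1 to 318 ± 135 CPM (SD, n = 3 each; log2 fold change 1.79), joins SNORA17A, SNORA17B and 3 more genes. Over all genes tested 0 passed with 6 libraries and 5 rose in the 5-library fit, where 11 rose and 4 fell when adjusted over the list alone. Camera called the list upward (adjusted p = 3.75e-05, and 0.00201 in the 5-library fit), and adjusted p = 0.883 with an estimated correlation. On gene TPM sums, the direction of the list was reversed and the call lost (adjusted p = 0.571).

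Among 26 measured genes of the integrated stress response, 19 had a log2 fold change above 0 and the median was 0.05 (16 and 0.16 in the 5-library fit). ATF4 was the 1 that passed adjusted over the list alone. The amino acid transporter gene SLC3A2 (402 ± 26.1 to 670 ± 165 CPM, SD, n = 3 each; log2 fold change 0.74) and DDIT3, counted with an overlapping gene (log2 fold change 0.89, and 0.52 in the 5-library fit), did not pass with 6 libraries. In the 5-library fit, ATF4, SLC3A2, SLC7A5, DDIT3 and SLC7A11 passed adjusted over the list alone, 5 higher and 0 lower. TRIB3 and CHAC1, common targets of ATF4, had log2 fold changes of −0.03 and 0.09. Camera called the list upward at an adjusted p of 0.0442 (0.0155 in the 5-library fit), and adjusted p = 0.76 with an estimated correlation. That call was lost without control replicate 1 (adjusted p = 0.144), control replicate 3 (0.0697), UPF2 siRNA replicate 2 (0.323) or UPF2 siRNA replicate 3 (0.0663).

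Interferon-stimulated genes and cell cycle genes were lower as groups, by small amounts. Of 35 measured interferon-stimulated genes, 6 had a log2 fold change above 0 and the median was −0.17 (−0.38 in the 5-library fit). The antiviral sensors OAS1 (−0.87) and OAS2 (−0.60) and IFI44L (−0.61) were among 8 genes lower at an unadjusted p under 0.05, and BST2, the most abundant, had a log2 fold change of −0.09 (OAS2 −0.39 and BST2 −0.38 in the 5-library fit). Of 32 cell cycle genes, 4 were above 0 and the median was −0.16, with the replication helicase subunits MCM3 (−0.43) and MCM6 (−0.42) lowest and TOP2A, the most abundant, at −0.24. No member of either list passed edgeR's test, over all genes or adjusted over the list alone, with 6 or 5 libraries. Camera called both downward (adjusted p = 8.38e-04 and 9.92e-04, and 1.97e-04 and 0.00201 in the 5-library fit), and adjusted p = 0.883 for both with an estimated correlation. The interferon call was lost without UPF2 siRNA replicate 2 (adjusted p = 0.0771) and the cell cycle call without UPF2 siRNA replicate 3 (adjusted p = 0.0693).

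Of 15 NMD factors, UPF3B (log2 fold change 1.23, and 0.70 in the 5-library fit) and SMG9 (0.85) were higher and UPF2 lower when adjusted over the list alone. Camera did not call the list with 6 libraries (adjusted p = 0.832) and called it upward in the 5-library fit (adjusted p = 0.00892, and 0.797 there with an estimated correlation), where 8 factors, among them UPF1, SMG1, SMG5 and SMG6, rose when adjusted over the list alone. Replication-dependent histones had low mean levels in this poly(A)-selected RNA, at 7.13 CPM under control siRNA and 6.76 CPM under UPF2 siRNA. Camera called them downward in the 5-library fit (adjusted p = 0.0155, and 0.797 there with an estimated correlation) and not with 6 libraries (adjusted p = 0.53). The difference between these fits was not tested.

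The other 18 lists were not called. Their camera adjusted p values with 6 libraries were 0.538 for the exon junction complex, 0.832 for SR proteins and splicing regulators, 0.966 for the unfolded protein response, 0.53 for p53 targets, 0.538 for antigen presentation by MHC class I, 0.966 for ligands of immune receptors, 0.787 for inflammatory cytokines, 0.177 for DNA repair, 0.787 for apoptosis regulators, 0.53 for cholesterol synthesis, 0.691 for glycolysis and hypoxia, 0.0516 for mitochondrially encoded transcripts and 0.53 for the double-stranded RNA pathway. The mitochondrial list depended on single libraries: it was called upward without control replicate 1 (adjusted p = 0.0143), control replicate 2 (6.41e-04) or UPF2 siRNA replicate 3 (0.00423), and not without control replicate 3 (0.913), UPF2 siRNA replicate 1 (0.2) or UPF2 siRNA replicate 2 (0.58), with an adjusted p of 0.927 for 6 libraries with an estimated correlation. The markers of other cells gave 0.53 for epithelial, 0.449 for mesenchymal, 0.53 for immune, 0.99 for fibroblast and 0.832 for endothelial genes. ADM, in the hypoxia list, and COL3A1, a collagen gene in the fibroblast list that was counted with MIR3606 at 0.57 ± 0.02 and 1.45 ± 0.22 CPM, passed adjusted over the list alone. The most abundant members of immune-related lists had log2 fold changes of −0.18 for CANX, −0.30 for NT5E and 0.31 for CXCL8. The most abundant members of other lists had −0.23 for HNRNPA1, 0.02 for CALR, 0.17 for BAX, −0.18 for XRCC5, −0.22 for MCL1 (counted with an antisense gene), −0.05 for FDPS, −0.04 for H1-2, −0.23 for ADAR and 0.46 for MT-CO3 (counted with MT-ATP6 and MT-ATP8). Among markers, EPCAM had −0.56, VIM −0.06, COL1A1 −0.46 and ESAM 0.51, and CD68 could not be read because it is counted with EIF4A1 and other genes. Several of these values rest on UPF2 siRNA replicate 1. In the 5-library fit they were −0.17 for EPCAM, −0.18 for VIM, −0.12 for COL1A1, −0.13 for NT5E, −0.14 for HNRNPA1, −0.07 for MCL1, −0.23 for FDPS, −0.62 for H1-2 and −0.06 for ADAR, and the sign turned for CANX (0.12), CXCL8 (−0.03), CALR (−0.09) and BAX (−0.09). For the unfolded protein response, inflammatory cytokines, apoptosis regulators and fibroblast markers, the direction of the test and the sign of the median differed, and for endothelial markers the direction and the sign of the mean.

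Transcripts annotated with the NMD biotype shifted upward under UPF2 siRNA relative to other transcripts. Of 4744 tested, 257 were higher and 27 lower at an unadjusted p under 0.05, and in the 5-library fit these counts were 836 and 43. The other biotypes shifted upward in that fit as well, with 684 higher and 68 lower retained-intron, 773 and 118 processed and 1630 and 531 protein-coding transcripts, and medians of 0.113 to 0.229 against 0.287 for the NMD biotype. The NMD-biotype counts were 139 and 13 without control replicate 2, 171 and 11 without control replicate 3, 213 and 52 without UPF2 siRNA replicate 2 and 165 and 81 without UPF2 siRNA replicate 3, with medians of −0.088 and −0.073 in the last pair of fits, and 172 and 23 without control replicate 1. With libraries centred on their median, 350 NMD-biotype transcripts were higher and 83 lower, and 499 and 701 protein-coding ones (482 and 353 without centring). The clearest was an NMD-biotype transcript of SNRPA1, a U2 spliceosome component (ENST00000559309, chromosome 15, 101281514 to 101295282, GRCh38), which went from 3.35 ± 0.379 to 27 ± 1.05 TPM (SD, n = 3 each; log2 fold change of TPM + 0.5 of 2.84, SE 0.216). It rose past limma's test adjusted over the NMD biotype alone (adjusted p = 0.0237), the 1 transcript to do so, and not over all 59360 transcripts (adjusted p = 0.296). Chosen after their values were seen, NMD-biotype transcripts of the chaperone cofactor BAG1 measured 20.7 ± 0.137 and 45.4 ± 2.54 TPM, of the ribosome biogenesis factor EIF6 76.4 ± 9.70 and 162 ± 17.6 TPM, and of the splicing regulator HNRNPM 3.44 ± 0.719 and 12.7 ± 1.26 TPM (SD, n = 3 each). NMD-biotype transcripts of TMEM208, PSMA3, PFDN5, ETHE1, FLOT2, REXO2, RPL27A and GGCT, chosen likewise, had log2 fold changes between 1.38 and 1.98. The values of both groups did not overlap, with UPF2 siRNA higher, in 9.9% of NMD-biotype transcripts, and with UPF2 siRNA lower in 2.6%, where chance gives 5% each.

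Limma called 0 of 59360 annotated transcripts higher and 0 lower, with 1800 at an unadjusted p under 0.05, and 0 when any library was left out. The 1800 became 917 without control replicate 2, 949 without control replicate 3 and 5066 without UPF2 siRNA replicate 1. As a set, camera called NMD-biotype transcripts upward (adjusted p = 0.00363, and 2.43e-04 in the 5-library fit), and adjusted p = 0.841 with an estimated correlation. Protein-coding transcripts were called downward (adjusted p = 0.00979, and adjusted p = 0.841 with an estimated correlation) and retained-intron transcripts were not called (adjusted p = 0.257). Relative to the other transcripts of their genes, NMD-biotype transcripts were also called upward (adjusted p = 0.0255). In 6844 genes with both kinds, NMD-biotype transcripts held 7.37 ± 0.58% of the TPM under control siRNA and 7.69 ± 0.43% under UPF2 siRNA (SD, n = 3 each; exact permutation p = 0.5, 2-sided, where the smallest possible is 0.1).

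**Figure D4:**
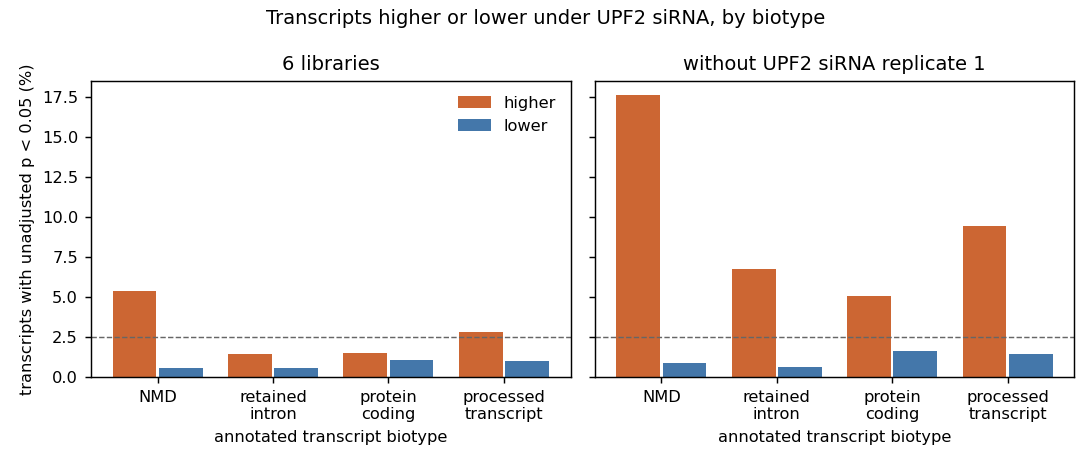
Percent of tested transcripts with an unadjusted limma p under 0.05 that were higher or lower under UPF2 siRNA (vertical axis), by annotated biotype (horizontal axis), with 6 libraries (left) and without UPF2 siRNA replicate 1 (right). The dashed line at 2.5% marks the share per direction that chance gives; with 6 libraries 5.42% of NMD-biotype transcripts were higher and 0.57% lower.

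With 6 libraries, exon usage passed the per-gene Simes test in PRKCSH, NAPA and RND3, and with a replicate block it passed in 0 genes. A wrong split of the libraries gave up to 61 such genes. Exon bin 71 of PRKCSH, which encodes a glucosidase II subunit, rose relative to the rest of its gene by 2.37 on the log2 scale (edgeR adjusted p = 5.60e-04). Its level went from 1.27 ± 0.433 to 6.56 ± 6.45 CPM (SD, n = 3 each), and UPF2 siRNA replicate 1 alone stood at 14 CPM. Bins 3, 4 and 5 of NAPA, a vesicle fusion adaptor counted with an overlapping gene, rose by between 2.06 and 2.37, and bin 14 of RND3, a small GTPase, by 3.22. UPF2 siRNA replicate 1 was highest here too. Bin 14 of RND3 stood at 1.09, 0.089 and 0.119 CPM in UPF2 siRNA replicates 1, 2 and 3, and bin 5 of NAPA at 6.37, 1.90 and 1.65 CPM. Bin 8 of CDKAL1, a tRNA-modifying enzyme, went from 0.329 ± 0.014 to 1.46 ± 0.845 CPM (SD, n = 3 each; relative log2 fold change 2.04, edgeR adjusted p = 0.0497). The remaining called bins were bin 47 of ANKRD28 and bin 63 of CSNK1E, the latter counted with TPTEP2. In the 5-library fit the bins of RND3 (edgeR adjusted p = 0.446), ANKRD28 (0.274) and CSNK1E (0.204) did not pass, and those of PRKCSH (0.00132), NAPA and CDKAL1 did. The relative changes were smaller in that fit, at 1.26 for PRKCSH, 1.33 to 1.65 for NAPA, 1.5 for CDKAL1, 1.44 for RND3, 1.83 for ANKRD28 (3.43 with 6 libraries) and 1.49 for CSNK1E (2.51). BAX, PPP1R14B (counted with an overlapping gene) and NOL4L came next by gene and did not pass. Coordinates of these bins are not given, since the deposited bins could not be placed on the annotation for these genes. Of 316206 bins in 13913 genes, 8 rose, 0 fell, and 3 genes passed the Simes test, with 6304 bins at an unadjusted p under 0.05 and 9 bins called by limma-voom. The 6304 became 3384, 2869 and 3475 without control replicates 1, 2 and 3, and 13969 without UPF2 siRNA replicate 2. Without UPF2 siRNA replicate 1, 239 bins rose and 41 fell, in 154 genes (110 genes passed the Simes test), and without any 1 control library no bin was called (48 bins without UPF2 siRNA replicate 2, and 5 without UPF2 siRNA replicate 3).

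No bin of UPF2 or of a reported NMD target passed with 6 libraries, while 22 bins in 8 of the 30 NMD target genes did in the 5-library fit (5 of the genes passed the Simes test). In TRA2B, a splicing regulator whose own message is a known NMD substrate, bin 34 measured 2.40 ± 0.458 CPM (SD, n = 3) under control siRNA and 21, 6.68 and 6.18 CPM in UPF2 siRNA replicates 1, 2 and 3, with a relative change of 1.08 in the 5-library fit (edgeR adjusted p = 0.00154). Bins 15 and 16 of RPS9, a ribosomal protein gene, rose by 1.63 and 1.46 in that fit. Most of the 22 bins lay in GAS5, where every called bin was lower relative to the gene. Bin 41 of GAS5, for example, stood at 1.04 ± 0.107 and 0.882 ± 0.322 CPM (SD, n = 3 each), while the whole gene went from 449 to 1210 CPM. The list of SR proteins and splicing regulators gave 8 called bins in 5 genes in that fit (3 passed the Simes test), including a bin of SRSF7 (relative change 1.88) and a bin of SRSF5 (1.65).

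Transcripts that StringTie assembled and that carry no reference identifier also shifted upward as a set. An assembled transcript at DNAJC2, a ribosome-associated chaperone (chromosome 7, 103312289 to 103344830, GRCh38), was listed at 0 in the controls and at 6.14, 5.59 and 4.67 under UPF2 siRNA. One at ARFRP1 (chromosome 20, 63699456 to 63708025, GRCh38) was listed at 0 in the controls and at 3.37, 3.00 and 3.25 under UPF2 siRNA. One at ORC6, an origin recognition complex subunit, measured 0.776 ± 0.144 and 5.42 ± 0.491, whereas one at FKBP8 measured 5.83 ± 1.36 and 0.063 ± 0.107 (deposited abundance, SD, n = 3 each). These 4 were chosen after their values were seen, and none passed the test (limma adjusted p from 0.148 to 0.292). Of 66933 transcripts, 11000 of them assembled only, limma called 0 higher and 0 lower. Among the assembled-only transcripts 471 were higher and 105 lower at an unadjusted p under 0.05. These counts were 2884 and 201 without UPF2 siRNA replicate 2, 582 and 219 without UPF2 siRNA replicate 1, 231 and 33 without control replicate 2 and 295 and 54 without control replicate 3. Camera called that set upward (p = 8.60e-06, and 0.0381 in the 5-library fit), with p = 0.0853 with an estimated correlation. Their share of the abundance was 7.20 ± 0.336% and 7.91 ± 0.712% (SD, n = 3 each; exact permutation p = 0.3, 2-sided, where the smallest possible is 0.1).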

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

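Gene TPM sums, the length trend, quality weights and DESeq2 on 5 libraries were chosen after the result was seen. Genes higher and lower under UPF2 siRNA numbered 46 and 6 with no filter (38465 genes tested), 115 and 36 with DESeq2, 25 and 3 with the length trend removed, 1188 and 927 with voom and library quality weights, and 417 and 208 with DESeq2 on the 5 libraries without UPF2 siRNA replicate 1. They kept to 0 and 1 with DESeq2 size factors, the stricter filter of 1 CPM, limma-voom and a 2-fold minimum, and on gene TPM sums, where the 1 gene was ENSG00000258073 and not UPF2. When each library was left out they ranged from 0 to 53 and from 0 to 5, with the highest values without UPF2 siRNA replicate 1. The length fit shared 27 of its 28 genes with the 58 of the 5-library fit, and DESeq2 on 5 libraries called all 58. In the simulation DESeq2 made more false calls than edgeR, and the cause of the other differences was not tested.

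The log2 fold change of UPF2 was −1.54 on gene TPM sums and ranged from −2.18 to −1.97 when each library was left out. Its fits of 5 libraries have fewer samples, and the fit without UPF2 siRNA replicate 1 was the only one of them that called it. Of 392 comparisons of named genes other than UPF2 over the alternatives, 280 stayed uncalled and 112 passed the threshold newly, and none reversed. These genes were named because they passed in the 5-library fit or adjusted over a list alone. That fit is among the alternatives, so part of the 112 was fixed by the choice of genes. All 132 comparisons of named annotated and 96 of named assembled transcripts stayed uncalled in the same direction. These transcripts were chosen for groups that do not overlap, so leaving out a library could not reverse their direction. Of 72 comparisons for named exon bins, 29 stayed called and 43 lost the call.

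Of 25 lists, 5 were called, against 0 with an estimated correlation, 0 with fry and 3 to 7 when each library was left out (3 without UPF2 siRNA replicate 2, 7 without UPF2 siRNA replicate 1). Adjusted p with an estimated correlation was 0.76 for NMD targets and the integrated stress response, and 0.883 for small nucleolar RNA hosts, interferon-stimulated genes and cell cycle genes. With fry it was 0.292 for NMD targets and the stress response, 0.359 for host genes and cell cycle genes, and 0.579 for interferon-stimulated genes. The stress response had 0.129 with no filter, where DNA repair genes were called downward (0.0402). Mitochondrially encoded transcripts, at 0.0516 in the 6 libraries, were called upward with DESeq2 size factors (0.0487), the filter of 1 CPM (0.0206) and gene TPM sums (0.0143), and ranged from 6.41e-04 to 0.913 when each library was left out, with 0.927 at an estimated correlation. With each library left out the adjusted p of the stress response ranged from 0.00875 to 0.323, that of interferon-stimulated genes from 2.22e-07 to 0.0771, and that of cell cycle genes from 3.69e-04 to 0.0693. Host genes reversed on gene TPM sums (0.571). NMD-biotype transcripts had 0.841 with an estimated correlation, adjusted over the biotypes. With the length trend removed as well, their camera p was 0.0168, unadjusted and for this set alone, so these values cannot be compared. The cause of these differences was not tested.

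Genes with changed exon usage numbered 5 with no filter, 5 with a mean of at least 10 counts, 5 with limma-voom and 57 with the gene-level F test. With each library left out, bins ranged from 0 to 280 and genes from 0 to 110, with the highest values without UPF2 siRNA replicate 1.

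Same-numbered libraries correlated at −0.18, 0.44 and −0.09 in their deviations from the group means. With 3 libraries per group, these values cannot settle whether replicate numbers pair the libraries. With the replicate block, 0 genes were lower, UPF2 had a log2 fold change of −2.08 (edgeR adjusted p = 0.789), the stress response an adjusted p of 0.101, and 0 exon bins and 0 genes with changed usage were called. The mitochondrial list was called upward with it (adjusted p = 0.00274). Fits on estimated counts of transcripts (edgeR, DESeq2, size factors, a minimum of 10 counts, shares from counts) were not run, since the table holds no counts, and the lane could not be varied.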

Other observations

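Tests chosen only after the result was seen were those of gene classes, of the length trend for UPF2 siRNA replicate 1 and for the NMD targets, of EPCAM, of a wrong label, of NMD targets without UPF2 siRNA replicate 1, of NMD-biotype transcripts relative to their genes, and the splits for edgeR, for the length fit and for quality weights.

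Transcribed pseudogenes tended to be higher under UPF2 siRNA. SEPTIN7P2 measured 8.24 ± 0.269 and 23.3 ± 2.77 CPM (SD, n = 3 each), RP9P 4.18 ± 0.642 and 13.2 ± 4.10 CPM, CIDECP1 8.15 ± 0.094 and 17.6 ± 1.49 CPM, and AFG3L1P 45.4 ± 4.56 and 94.7 ± 12.6 CPM. Their edgeR adjusted p values ran from 0.0914 to 0.183 in these 6 libraries, so none passed, and from 0.0126 to 0.0217 in the 5-library fit. Transcribed pseudogenes made up 10 of the 53 genes that rose there (18.9%, against 2% of the genes tested), which prompted the hypothesis that they rise as a class, as may follow from transcripts with premature stops escaping decay. It was tested on the 397 others, in the same libraries. Camera gave p = 0.00207 upward, 0.00186 in the 5-library fit, 0.0434 with the length trend removed and 0.0566 with an estimated correlation, so the call was lost at the last. Reads shared with parent genes were not separated. Other pseudogenes were not called, with a camera p of 0.104. With 6 libraries, camera called long non-coding RNAs upward with a p of 6.98e-04 and protein-coding genes downward with a p of 4.79e-04, but neither in the 5-library fit, with p values of 0.569 and 0.756, nor with an estimated correlation (0.412 and 0.0853).

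Why UPF2 siRNA replicate 1 stood apart was weighed first. A wrong label is argued against by its UPF2 level of 6.79 CPM, near those of the other UPF2 siRNA libraries. A length trend alone is argued against as the whole cause, since its root mean square log2 distance to the nearest library stayed at 0.671 with the trend removed (0.747 before), above the 0.526 of the next library. Loss of the 5′ part of long transcripts may contribute, with a median log2 5′ to 3′ ratio of −1.65, although the labels give an RNA integrity number above 9. Fewer EpCAM-high cells in that library could be a further part, since EPCAM stood at 130 CPM in the last 25% of its abundant exon bins, against 316 to 465 CPM in the other libraries, but its own 5′ to 3′ ratio was shifted too (−0.44).

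For the higher NMD target genes, 3 technical explanations were weighed with camera at the preset correlation. Camera still called the list with the length trend removed (adjusted p = 3.53e-06), without UPF2 siRNA replicate 1 (adjusted p = 1.97e-04), and on the 21 members counted alone (p = 6.19e-06; 0.0406 with an estimated correlation). Of those 21, 20 were above 0. At the preset correlation camera also gave p values down to 5.30e-05 for the whole list under wrong splits of the libraries. The 3 versions given here were not run on splits, so their calls alone cannot decide against the 3 explanations. The median log2 fold change did stay above 0. It was 0.34 with the length trend removed, 0.4 without UPF2 siRNA replicate 1 and 0.35 for the members counted alone. The separate lanes stay open, as does correlation among the list's genes. Camera with an estimated correlation ended the call over all 25 lists (adjusted p = 0.76). The stress response lost its call there too, at an estimated correlation of −0.002, so for that list the loss need not come from correlation. This does not carry over to the NMD targets, with an estimate of 0.164. Nor does it to host genes (0.315), interferon-stimulated genes (0.232) or cell cycle genes (0.22). Reduced decay of the NMD target transcripts under UPF2 siRNA is the biological explanation that the design names, and it stays untested.

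For NMD-biotype transcripts, a length trend is argued against as the whole cause by limma's camera with the trend removed, with a p of 0.00147 (0.0168 with an estimated correlation). A rise of the whole output of their genes is argued against only by camera relative to the other transcripts of each gene (adjusted p = 0.0255). That test was not run with an estimated correlation. Within genes with both kinds, the NMD-biotype share of TPM was 7.37% under control siRNA and 7.69% under UPF2 siRNA (exact permutation p = 0.5, 2-sided). A rise of all isoforms that are not protein-coding could not be excluded. Against retained-intron and processed transcripts of matched length and abundance, limma's camera gave a p of 0.141 (0.0322 in the 5-library fit), although 257 NMD-biotype and 102 matched transcripts were higher at an unadjusted p under 0.05. The lane cannot be told apart from the siRNA here either.

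The 6 libraries split into 3 and 3 in 10 ways, too few for a share under 0.05. The real split gave 1 gene with edgeR and 0 in the highest other, so 1 of the 10 splits gave as many. With the length trend removed it gave 28 and 0 (1 of the 10 splits). The camera p was 4.83e-08 for NMD targets (5.30e-05 in the next split) and 9.08e-04 for NMD-biotype transcripts (0.00477 in the next), again 1 of the 10 each. For NMD targets the camera p was also under 0.05 in further wrong splits (4.98e-04, 6.48e-04, 0.0106, 0.0135 and 0.0381). It was not in the rest (0.629, 0.867 and 0.936). With DESeq2, 2 splits gave at least as many as the real 151, and the split that put control replicate 1 with UPF2 siRNA replicates 2 and 3 gave 238. With quality weights, 2 splits reached the real 2115, with 2451 in the highest other. For lists, 3 splits reached the real 5, and the other splits called from 2 to 5 lists each. Camera at the preset correlation thus called lists under every wrong split too. For exon bins 3 splits reached the real 8, and the split that put control replicates 1 and 2 with UPF2 siRNA replicate 2 gave 191. For genes with changed usage 3 splits reached the real 3, with 61 in the highest other. Exon counts that large under a wrong split may point to a structure of the samples other than the siRNA. The split with 191 bins separated the libraries by their trend over transcript length. Spearman correlations of gene deviations with length were 0.35, 0.28 and 0.35 in control replicates 1 and 2 and UPF2 siRNA replicate 2. They were −0.09, −0.51 and 0.08 in control replicate 3 and UPF2 siRNA replicates 1 and 3. False calls of the test stay open too, since it called 129 unchanged bins in a simulation where each bin kept its own spread. For annotated and for assembled transcripts all 10 splits gave 0.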
